A study of Drosophila melanogaster with 21 samples.

How the data were processed

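The labels listed 21 samples from Drosophila melanogaster brain. Bulk RNA-seq (7 libraries) and bulk ATAC-seq (6 libraries) were made from L1 lamina neurons isolated by fluorescence-activated cell sorting (FACS) from wild-type pupae at 40 h, 60 h and 72 h after puparium formation. The markers of the sort were not given. Libraries followed SMART-seq2 for RNA and a modified Buenrostro protocol for ATAC, per the labels. The remaining 8 samples, single-cell libraries of which 6 were labelled with perturbations of the ecdysone receptor or of Hr3 and 2 with none, were not analysed here. The 13 bulk libraries formed 6 groups: RNA with n = 2, 3 and 2 at 40 h, 60 h and 72 h, and ATAC with n = 2 at each age.

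The RNA table was deposited in RPKM (reads per kilobase of gene, scaled per library), per the file headers, with 7076 genes kept by a filter that was not stated. The size to which each RNA library was scaled is called its effective size below. The unit of the ATAC table was not labelled. From the deposited values it was read as RPKM of each peak: level times peak width gave whole multiples of 1 step per library (within 0.1 of a read for 100% of values). The ATAC scaling was to the reads in peaks, with library factors whose in-peak totals multiplied to 1. Peaks (26121, median width 459 bp, from 200 to 4252 bp) had been called once on merged libraries, per the peak names, and the authors gave the nearest gene and its distance per peak. Bowtie2 2.2.9, MACS2 2.1.1, bedtools, edgeR 3.26.8, Cell Ranger 3.1.0 and Seurat 3.1.2 were named per the submitters' processing notes, without a role for each. The genome build was not given in the sources used here, and peak positions are printed as deposited.

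Depth was recovered from the deposited values, since the values of single-exon genes times gene length were whole multiples of 1 step per library (302 to 326 genes behind each step, tolerance 0.01 of a read). The effective RNA library sizes were 22.1 to 46.1 M reads, and 7074 of 7076 genes gave whole reads, 22.5 to 39.5 M reads per library. Recovered reads over effective size were 0.86 and 0.83 at 40 h, 1.01, 1.02 and 1.00 at 60 h, and 1.19 and 1.10 at 72 h. The RNA scaling was therefore not to total reads alone, and it shifted with age against the recovered reads. For ATAC the effective sizes were 13.8 to 18.3 M reads and the reads in peaks 12.7 to 19.8 M. The median was 1132 reads per gene and library and 296 reads per peak and library, and chi-square per degree of freedom between libraries of 1 age was 12.2 to 139, so spread between libraries exceeded counting error. At most 11 genes were at 0 in any RNA library. Reads of paralogs and of antisense genes may be shared, and how the authors counted them was not given.

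Gene symbols were matched to current names (6643 equal, 409 through a synonym, 24 unmatched). Genes with RPKM of at least 1 in at least 2 libraries were tested (6939; 137 were not). Peaks above the lowest 10% of mean level were tested (23508; 2613 were not). Values were taken as log2(value + 1), a scale that understates the change of features at low level. For each assay 1 limma fit over the 3 ages was made, with trended variance moderation and no block (lmFit, contrasts.fit and eBayes; 4 residual degrees of freedom for RNA and 3 for ATAC, prior 6.36 and 8.18). The contrasts were 60 h against 40 h, 72 h against 60 h, and 72 h against 40 h. Tests were two-sided, and Benjamini-Hochberg adjusted p under 0.05 was the threshold per contrast. For ATAC the design before the data were examined had named a test by unit, and the RPKM unit led to limma. The p-values measure only the spread between these libraries, whose nature as biological or technical replicates was not stated.

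The following choices were made before the data were examined: tests, samples, filters, gene lists, named genes and the first set of alternatives. The 25 lists comprised 17 of gene groups and 8 of cell type markers. The groups were ecdysone response, dpr, DIP, beat and side, adhesion and guidance, presynaptic, transmitter receptor, voltage-gated channel, innexin, axon growth and cytoskeleton, lamina neuron transcription factor, heat shock, activity-regulated, cytosolic ribosome, oxidative phosphorylation, vacuolar ATPase and proteasome genes. The markers were those of glutamatergic neurons, other lamina neurons, GABAergic and monoaminergic neurons, glia, photoreceptors, hemocytes, progenitors, and muscle and fat body. Lists with at least 5 tested members (19) were tested with camera at a preset correlation of 0.01, with an estimated correlation as an alternative. A call lost in that alternative need not come from correlation between members, since some lists with an estimate below 0.01 lost theirs too. Camera compares the members with the other genes. Members were also counted as called over all genes and adjusted over the list alone. Some genes stood in more than 1 list, such as Vha100-1, VGlut, stan, Hr38, cac and bab2.

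Named genes were, per RNA contrast, the 8 largest rises and 8 largest falls past the threshold with mean RPKM of at least 10, no overlap between the values of the ages compared and a symbol other than a bare CG or CR number. Up to 4 members per list with the smallest p and 12 genes fixed by name were added (EcR, Hr3, Hr39, ftz-f1, Eip93F, br, Eip74EF, Eip75B, VGlut, ort, svp and brp); br was not among the genes tested. Genes already named for a step were not all repeated for 72 h against 40 h. Named peaks were the 4 largest openings and closings per contrast and the smallest-p peak at each of EcR, Hr3, ftz-f1, Eip93F, Eip74EF and Eip75B. A closing peak next to a transfer RNA gene was left out.

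Peaks and RNA were joined by the nearest gene given by the authors (8580 genes, 5367 of them in the RNA table). The mean log2 change of a gene's peaks was compared between genes whose RNA rose and fell by a two-sided permutation test over genes (100000 resamples). Genes called in both steps were counted beside the overlap of independent lists and beside 100 simulations of unchanged groups that shared the 60 h libraries. Sites of 7 motifs had been planned but were not tested, because no genome sequence was used here.

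The fit was tested on simulated data with the median spread of these libraries at each level and 50 changed features per size. Features of larger spread were not simulated and far fewer features changed than were called in the data, so recovery in the data may differ. Of these, 35, 38 and 29 were recovered at 2-fold for RNA in the order of the contrasts, and 36, 35 and 33 for ATAC. At 1.5-fold the numbers were 12, 18 and 13 for RNA and 3, 9 and 6 for ATAC. False calls among unchanged features were 8, 15 and 8 for RNA and 4, 6 and 5 for ATAC. At an unadjusted p under 0.05, camera called 0 of 100 lists of unchanged simulated genes in each contrast. The simulated lists did not keep the correlation between members of the real lists, estimated at -0.11 to 0.66. That count therefore cannot show how often camera calls unchanged lists whose members are correlated. For the difference of medians, the permutation test called 2 of 40 simulated null cases and 40 of 40 with a planted difference of 0.5.

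Alternatives covered the pseudocount, filters, quantile and median-ratio scaling, median and loess centring, replicate block, only the ages compared, a log2 change of at least 1, voom on recovered reads, fry and leaving out each library. For RNA the replicate block gave 60 h replicate 3 a term of its own, so that library did not bear on the changes between ages. Those chosen after seeing the data were voom, loess centring, leaving out 60 h RNA replicates 1 and 2 together, leaving out 60 h ATAC replicate 2 from the join of peaks and RNA, leaving out chromosomes Y and 4, and a block with exchanged numbers. R 4.3.3 with limma 3.58.1 and Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.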

Results

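The data described how gene expression and open chromatin of L1 neurons, lamina neurons that receive photoreceptor input, changed in the second part of pupal development. Bulk RNA-seq covered L1 neurons sorted at 40 h, 60 h and 72 h after puparium formation (n = 2, 3 and 2 libraries), and bulk ATAC-seq the same ages (n = 2 each). Effective library sizes were 22.1 to 46.1 M reads for RNA and 13.8 to 18.3 M reads for ATAC. On the log2 scale RNA libraries of 1 age correlated at 0.976 to 0.987 across genes. ATAC libraries correlated at 0.968, 0.842 and 0.861 across peaks at 40 h, 60 h and 72 h. The first principal component held 67.9% of the RNA variance and 78.7% of the ATAC variance. ATAC replicate 2 at 60 h lay at 42.8 on that component and replicate 1 at 11.7, with the 72 h libraries at 62.7 and 76.5.

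From 40 h to 60 h, the comparison that spans the first interval, regulators of the ecdysone cascade turned over. The nuclear receptor gene ftz-f1 rose from 0.618 ± 0.24 (SD, n = 2) to 54.3 ± 11 RPKM (SD, n = 3), a log2 change of 5.08 ± 0.19 (SE, adjusted p = 1.1e-08). Blimp-1, which encodes a transcriptional repressor induced by ecdysone, fell by 5.69 ± 0.24 on the log2 scale, from 81.4 ± 7.2 to 0.604 ± 0.17 RPKM. The early and early-late nuclear receptor genes Hr4 and Eip75B fell by 4.12 ± 0.16 and 2.50 ± 0.13. Transcripts of Eip74EF and Hr39 fell by 1.94 ± 0.26 and 2.48 ± 0.33. The ecdysone receptor gene EcR fell by 0.55 ± 0.16 (adjusted p = 0.014), a call lost without 40 h replicate 1 and without 60 h replicates 1 and 2. Hr3 and Eip93F did not pass the threshold (-0.56 ± 0.32 and -0.36 ± 0.27, adjusted p = 0.19 and 0.29). Of the 17 tested members of the ecdysone response list, 2 rose, 10 fell and 5 did not pass, with the same counts adjusted over the list alone. The list's median change was -0.63 (camera adjusted p = 0.019; adjusted p = 0.22 with an estimated correlation).

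**Figure D1:**
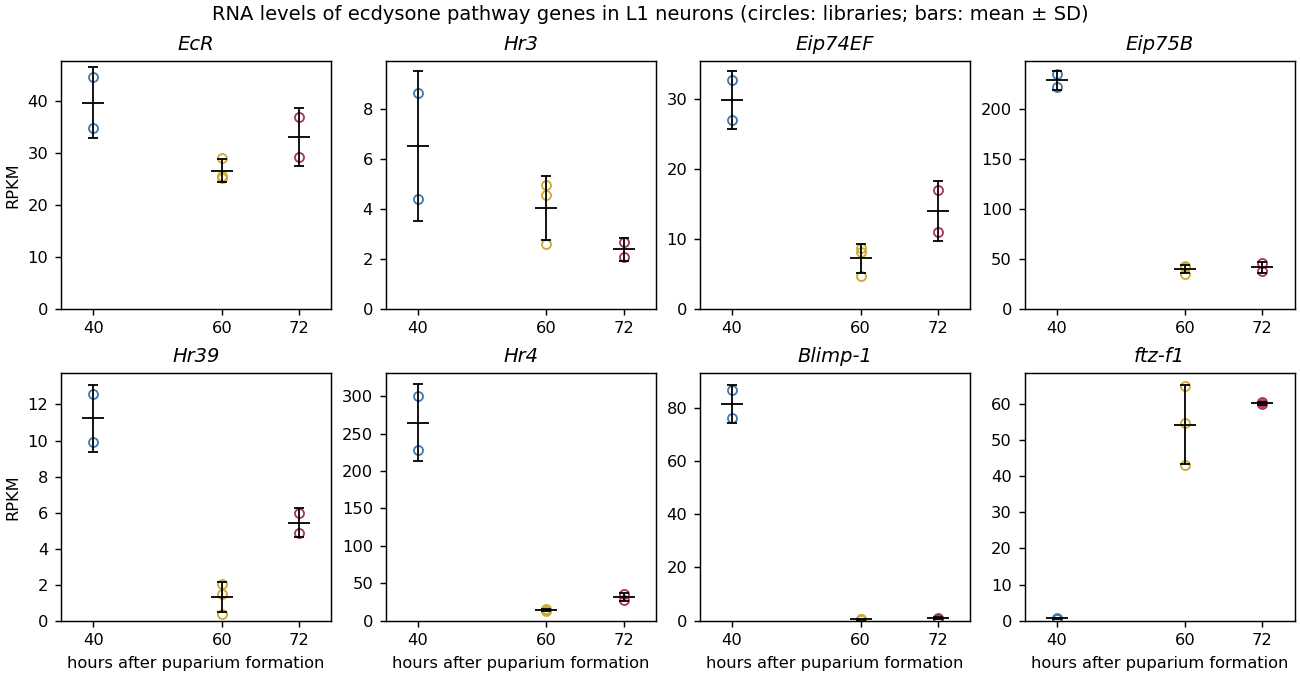
RPKM of EcR, Hr3, Eip74EF, Eip75B, Hr39, Hr4, Blimp-1 and ftz-f1 (vertical axes) at 40 h, 60 h and 72 h after puparium formation (horizontal axes); circles are libraries and bars are means with SD (n = 2, 3 and 2). ftz-f1 went from 0.618 to 54.3 RPKM between 40 h and 60 h, and Blimp-1 from 81.4 to 0.604 RPKM.

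Outside that list, the largest rises at 60 h included Pka-C3, a catalytic subunit of cAMP-dependent protein kinase (6.19 ± 0.14 on the log2 scale; 1.62 ± 0.49 to 189 ± 21 RPKM). The sodium/calcium-potassium exchanger Nckx30C rose by 6.14 ± 0.16 and the potassium-chloride cotransporter kcc by 5.85 ± 0.15. The other large rises were s-cup (6.18 ± 0.12), wry (5.81 ± 0.23), the receptor tyrosine kinase-like Drl-2 (5.63 ± 0.19), the co-chaperone stv (5.41 ± 0.13) and the adhesion protein Con (from 1.26 to 90.2 RPKM). The largest fall was that of Lac, an immunoglobulin-family adhesion protein, from 840 ± 180 to 4.63 ± 3.4 RPKM (-7.40 ± 0.42, adjusted p = 2e-07). Dyrk2 (-6.02 ± 0.23), lncRNA:CR44978 (-5.99 ± 0.27), ImpL1 (-5.55 ± 0.57), the Rab effector Rph (-5.37 ± 0.20), the cell death gene hid (-5.12 ± 0.26) and Hsp27 (-5.01 ± 0.17) also fell.

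Cell surface genes moved in both directions. Of 70 tested adhesion and guidance genes, 10 rose and 36 fell (10 and 37 adjusted over the list alone), and 24 did not pass. Their median was -0.77 (camera adjusted p = 1.9e-04; adjusted p = 0.099 with an estimated correlation). The Wnt receptor gene fz fell by 4.63 ± 0.19 (114 to 3.65 RPKM), and the integrin subunit mew rose by 3.82 ± 0.17. Among 19 dpr genes, which encode immunoglobulin-domain surface proteins, 8 rose and 2 fell, also when adjusted over the list alone (median 0.17, camera adjusted p = 0.17; called with fry, adjusted p = 5.9e-04). dpr5 rose from 5.36 to 187 RPKM, dpr2 from 12.6 to 269 RPKM, and dpr15 fell from 137 to 3.69 RPKM. Of their DIP partners, DIP-gamma fell (7.54 to 0.350 RPKM) and DIP-beta did not pass (-0.56 ± 0.38, adjusted p = 0.25). In the beat and side families 1 of 14 members rose, beat-VI (2.93 ± 0.11), and 3 fell, among them side (-4.35 ± 0.25), with camera adjusted p = 0.47. Of 5 innexins, the gap junction genes, 3 fell (Inx3, shakB and Inx5), calls that were lost without 60 h replicates 1 and 2 (camera adjusted p = 0.16).

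Of 39 presynaptic genes 28 rose and 4 fell (29 and 4 adjusted over the list alone), with a median of 0.82 (camera adjusted p = 4.3e-05; adjusted p = 0.44 with an estimated correlation). Synaptogyrin (Syngr) rose from 8.30 ± 3.4 to 219 ± 12 RPKM, and the dynamin gene shi and the NSF gene comt rose by 1.84 ± 0.13 and 1.69 ± 0.13. The active zone gene brp did not pass (-0.09 ± 0.12, adjusted p = 0.59). Of 28 voltage-gated channel genes 18 rose and 1 fell, with a median of 0.96 (camera adjusted p = 4.3e-05; adjusted p = 0.51 with an estimated correlation). unc79 (2.58 to 95.1 RPKM), the hyperpolarization-activated channel Ih (16.5 to 322 RPKM) and Hk (2.60 ± 0.13) were among them. Of 29 transmitter receptor genes 12 rose and 5 fell (camera adjusted p = 0.076), a list called under quantile normalization, with fry, without 40 h replicate 2 and without 60 h replicates 1 and 2. DopEcR, a receptor for dopamine and ecdysteroids, rose by 4.51 ± 0.10, the GABA receptor subunit Lcch3 by 1.91 ± 0.11, and the histamine-gated chloride channel ort from 4.50 ± 0.73 to 20 ± 6.1 RPKM. Of 43 axon growth and cytoskeleton genes 5 rose and 21 fell, with a median of -0.51 (camera adjusted p = 4.3e-04; adjusted p = 0.099 with an estimated correlation). The actin regulators pod1 and tsr fell from 114 to 15 RPKM and from 650 to 140 RPKM, and the stathmin gene stai fell by 1.66 ± 0.10.

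Oxidative phosphorylation genes rose together: 61 of 63 rose and 0 fell (62 and 0 adjusted over the list alone), with a median of 1.06 (camera adjusted p = 1.2e-21; adjusted p = 0.29 with an estimated correlation). UQCR-Q, for example, went from 213 ± 12 to 526 ± 2.7 RPKM. Of 16 vacuolar ATPase genes 15 rose, with a median of 1.33 (camera adjusted p = 3.4e-08; adjusted p = 0.29 with an estimated correlation); Vha13 rose by 1.97 ± 0.11. Ribosome genes (0 of 84 rose, 8 fell; 0 and 1 adjusted over the list alone) and proteasome genes (4 of 31 rose, 2 fell; 2 and 0 adjusted over the list alone) were not called by camera (adjusted p = 0.53 and 0.55). Under quantile normalization 42 ribosome genes fell and the proteasome median turned from 0.07 to -0.17, with both lists called down by camera (adjusted p = 3.5e-07 and 0.028).

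Of 17 tested lamina neuron transcription factor list genes 8 fell and 0 rose (median -0.38, camera adjusted p = 0.019; adjusted p = 0.22 with an estimated correlation). The list's camera call was lost without 60 h replicates 1 and 2. The pan-neuronal RNA-binding gene elav fell by 1.44 ± 0.13 and dac had a change of -1.19 ± 0.12, whereas svp, a gene expressed in L1, had -0.07 ± 0.11 (adjusted p = 0.62) and -0.32 under quantile normalization. VGlut, the transporter gene of glutamatergic neurons and the 1 member of that list, rose by 0.53 ± 0.14 (216 to 312 RPKM), but had 0.09 and did not pass under quantile normalization, and did not pass without 40 h replicate 1. Heat shock genes split (5 of 12 rose, 4 fell; 6 and 4 adjusted over the list alone; camera adjusted p = 0.83), with Hsp23 falling from 2090 ± 9.4 to 298 ± 120 RPKM. Of 6 activity-regulated genes 0 rose and 1 fell, CG17778, a call lost without 40 h replicate 2 (camera adjusted p = 0.92).

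Markers of other cells were measured in the same libraries. Of 13 photoreceptor genes 4 rose and 1 fell (median 1.10, camera adjusted p = 0.16), and their levels differed between the 60 h libraries. The list was called without 40 h replicate 2 and without 60 h replicate 3. It was also called with a replicate block, which takes 60 h replicate 3 out of the changes as well. The photoreceptor surface protein gene chp had 98.3, 186 and 19.7 RPKM in replicates 1, 2 and 3, and the light-gated channel gene trp 64.5, 124 and 16.7 RPKM. Among 11 glial genes 1 rose, the GABA transporter Gat (1.75 to 24.0 RPKM; camera adjusted p = 0.80). Of 6 genes of other lamina neurons 1 rose (0 adjusted over the list alone; camera adjusted p = 0.83). Of 4 tested hemocyte genes 1 rose, crq, and 2 fell, Col4a1 and vkg, while Hml reached at most 0.454 RPKM in any library. Of 4 GABAergic and monoaminergic genes DAT alone rose (0 adjusted over the list alone; lost with a replicate block), 0 of 2 progenitor genes (stg and grh) passed, and 0 muscle and fat body genes were tested.

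In this step 3312 of 6939 genes passed the threshold, 1748 higher and 1564 lower, and 8 of the 19 lists tested were called by camera (0 with an estimated correlation). Leaving out 60 h replicates 1 and 2, an alternative chosen after seeing the data, left 2129 genes (1174 higher and 955 lower). Of 86 named genes past the threshold 15 lost their call in that setting, among them EcR, VGlut, slp1, eya, beat-IV, Col4a1 and vkg. In that setting 1 library was left at 60 h. List medians were then 1.04 for oxidative phosphorylation (1.06 with all libraries), 1.32 for vacuolar ATPase (1.33), 0.84 for presynaptic (0.82) and 1.16 for channel genes (0.96). They were -0.81 for adhesion (-0.77), -0.39 for axon growth (-0.51) and -0.71 for ecdysone response genes (-0.63). With all libraries, median, mean and camera direction differed in sign for other lamina neurons (-0.0004, 0.16 and up) and heat shock genes (0.50, -0.004 and up).

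Between 60 h and 72 h, the second interval, the largest rises included ort and 3 genes known from glia. The histamine receptor gene ort, through which lamina neurons receive photoreceptor signals, rose from 20 ± 6.1 (SD, n = 3) to 723 ± 170 RPKM (SD, n = 2), by 5.14 ± 0.25 on the log2 scale (SE, adjusted p = 9.7e-07). e (ebony), Gs2 (glutamine synthetase 2) and nrv2, which are known from glia, rose by 6.51 ± 0.41, 5.21 ± 0.49 and 4.65 ± 0.32. Their 2 libraries at 72 h were unequal: Gs2 had 220 and 825 RPKM, and nrv2 153 and 335 RPKM. Nepl15 (5.84 ± 0.32), Tsp42Eg (5.06 ± 0.43), Hexo2 (4.66 ± 0.45) and the formin gene Fhos (4.59 ± 0.30) also rose, with the call of Tsp42Eg lost with voom. In the 72 h libraries Tsp42Eg had 24.3 and 85.0 RPKM and Hexo2 35 and 78.1 RPKM.

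Among the largest falls was that of the synaptic cleft protein gene hig, from 834 ± 270 to 31.2 ± 3.0 RPKM (-4.65 ± 0.21), and the guidance receptor robo3 fell from 203 ± 28 to 8.85 ± 7.8 RPKM. Oatp26F (-4.57 ± 0.31), Tbh (-4.39 ± 0.48), hbs (150 to 7.5 RPKM), Dyb (-3.60 ± 0.26) and Obp99a (-3.73 ± 0.66, lost with voom) fell too. wry, among the largest rises of the first interval, fell by 3.98 ± 0.23. The potassium channel gene Shawl fell by 3.12 ± 0.17 and the kainate-type receptor KaiR1D from 362 ± 16 to 68.8 ± 18 RPKM.

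The ecdysone regulators mostly did not pass in this step: 3 of 17 rose, 1 fell and 13 did not pass, also when adjusted over the list alone (camera adjusted p = 0.48). Hr4 rose by 1.10 ± 0.16, Hr39 by 1.55 ± 0.33 and Eip74EF by 0.88 ± 0.26 (adjusted p = 0.026, lost with a replicate block and without 60 h replicate 3 or 72 h replicate 1), and crol fell by 0.69 ± 0.14. ftz-f1 stayed near its 60 h level (60.2 ± 0.44 RPKM; 0.17 ± 0.19, adjusted p = 0.56). EcR (0.30 ± 0.16), Hr3 (-0.55 ± 0.32), Eip75B (0.06 ± 0.13), Eip93F (0.46 ± 0.27) and svp (0.18 ± 0.11) did not pass either. A difference between the steps in these genes was not tested.

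Of 39 presynaptic genes 20 rose and 6 fell (21 and 7 adjusted over the list alone; median 0.46, camera adjusted p = 0.0080; adjusted p = 0.67 with an estimated correlation). The list's call was lost under quantile normalization and with fry. Syngr rose to 827 ± 160 RPKM and the endophilin gene EndoA by 1.00 ± 0.13, while brp fell by 1.09 ± 0.12 (49.9 to 23 RPKM) and the synapsin gene Syn by 1.18 ± 0.11. VGlut rose by 0.95 ± 0.14, from 312 to 609 RPKM. Of 29 receptor genes 11 rose and 6 fell (11 and 7 adjusted over the list alone; camera adjusted p = 0.46), with nAChRalpha7 falling from 69.3 to 7.24 RPKM and Nmdar1 from 48.0 to 14.9 RPKM. Of 28 channel genes 6 rose, among them Shal (1.44 ± 0.15), and 2 fell (camera adjusted p = 0.19).

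Adhesion and guidance genes again went both ways, 12 rising and 25 falling of 70 (camera adjusted p = 0.11; called with fry, adjusted p = 0.0039), with comm (-1.59 ± 0.11), jeb (-3.16 ± 0.23) and Con (-2.37 ± 0.17) among the falls. Of 19 dpr genes 5 rose and 6 fell (6 and 6 adjusted over the list alone; camera adjusted p = 0.76). dpr18 rose from 34.9 to 143 RPKM, and dpr5, which had risen in the first interval, fell to 58.2 RPKM. Neither DIP gene passed. Of 14 beat and side genes 2 rose, side-VIII (1.08 ± 0.18 to 49.9 ± 38 RPKM, with 22.8 and 77.1 RPKM in the 72 h libraries) and side-IV (2.69 ± 0.27; camera adjusted p = 0.34, called with fry, adjusted p = 0.031). Of 43 axon growth genes 7 rose and 15 fell (7 and 17 adjusted over the list alone; camera adjusted p = 0.12; called with fry, adjusted p = 0.0057); fax fell by 2.05 ± 0.18 and spir by 1.73 ± 0.13. Of 5 innexins 3 rose (Inx2, Inx3 and ogre, each lost without 60 h replicates 1 and 2) and shakB fell by 1.23 ± 0.15 (camera adjusted p = 0.46). Of 17 lamina neuron transcription factor genes 2 rose, bab2 and dac, and 2 fell, sim and hth (camera adjusted p = 0.46).

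Oxidative phosphorylation and vacuolar ATPase genes rose further. Of 63 oxidative phosphorylation genes 60 rose and 1 fell (61 and 1 adjusted over the list alone), with a median of 0.61 (camera adjusted p = 1.0e-19; adjusted p = 0.44 with an estimated correlation). Under quantile normalization 28 rose and 2 fell. Of 16 vacuolar ATPase genes 14 rose, with a median of 0.56 (camera adjusted p = 4.8e-06; adjusted p = 0.44 with an estimated correlation), and 6 rose under quantile normalization. ND-MLRQ rose from 814 ± 78 to 1662 ± 9.4 RPKM and Vha13 from 926 ± 71 to 1671 ± 110 RPKM. Proteasome genes fell: 23 of 31 fell and 0 rose (26 and 0 adjusted over the list alone), with a median of -0.55 (camera adjusted p = 9.1e-10; adjusted p = 0.44 with an estimated correlation). Prosalpha7 fell by 0.93 ± 0.11 and Prosbeta3 by 0.88 ± 0.10. Of 84 ribosome genes 7 rose and 4 fell (6 and 4 adjusted over the list alone; camera adjusted p = 0.51), while 43 fell under quantile normalization. Of 12 heat shock genes 6 fell, with Hsp23 (-2.77 ± 0.23) and stv (-1.38 ± 0.12) among them (median -0.38, camera adjusted p = 0.029; adjusted p = 0.67 with an estimated correlation). That list's call was lost with fry, without 60 h replicate 1, 60 h replicate 2 or 72 h replicate 2, and without 60 h replicates 1 and 2. Of 6 activity-regulated genes 1 rose, CG14186, and 2 fell, CG17778 and CG14024 (camera adjusted p = 0.46; called with fry, adjusted p = 0.0039).

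Of 11 glial genes 7 rose and 1 fell (median 1.5, camera adjusted p = 0.0019; adjusted p = 0.44 with an estimated correlation). The glial transcription factor gene repo rose from 1.00 ± 0.86 to 10.9 ± 8.2 RPKM, with 5.08 and 16.7 RPKM in the 72 h libraries, a call lost without 60 h replicates 1 and 2. Of 13 photoreceptor genes 1 rose, norpA, and 5 fell (median -0.86, camera adjusted p = 0.11). chp went from 101.4 ± 83 to 7.31 ± 6.8 RPKM. This list was called without 60 h replicate 3 and without 72 h replicate 2. It was also called with a replicate block, which takes 60 h replicate 3 out of the changes as well. Of 6 genes of other lamina neurons 3 rose, including ChAT (1.87 ± 0.26) and VAChT (1.27 ± 0.36), the cholinergic pair. That list was not called (camera adjusted p = 0.0504). It was called without 60 h replicate 3 and with a replicate block, settings that both take that library out of the changes. It was also called under quantile normalization, with fry, and without 60 h replicate 2 or 72 h replicate 1. Of 4 GABAergic and monoaminergic genes VGAT (22 to 74.9 RPKM) and Gad1 (0.310 to 4.56 RPKM) rose. Among hemocyte genes Pxn fell from 274 ± 86 to 43.7 ± 0.25 RPKM and crq rose by 0.70 ± 0.16, and 0 of 2 progenitor genes passed.

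**Figure D2:**
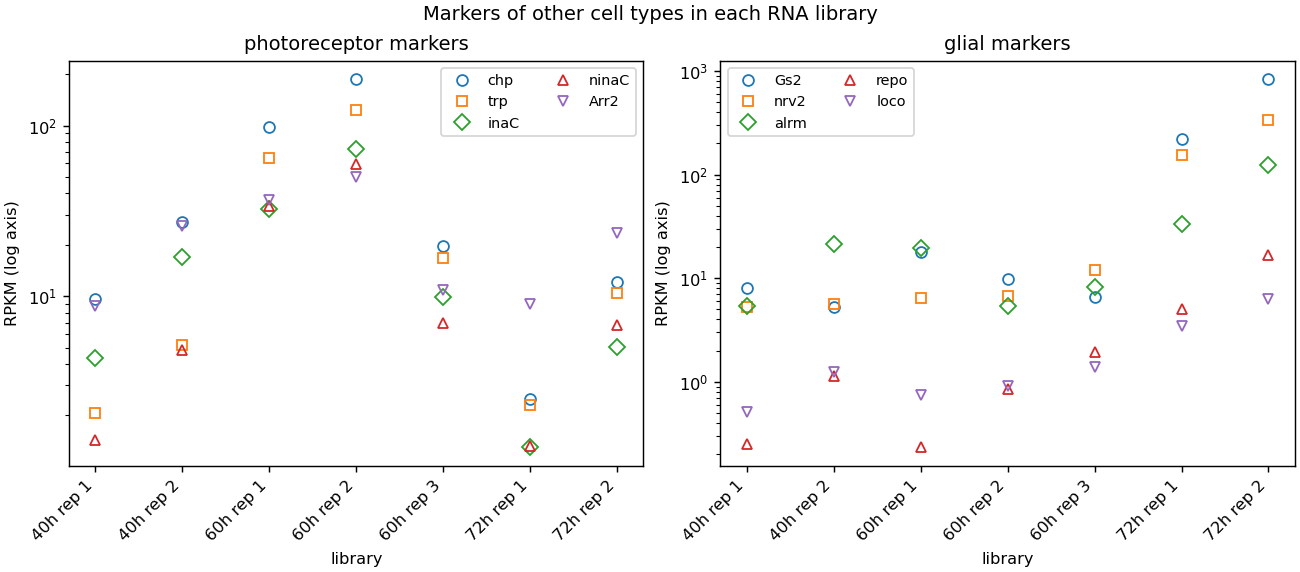
RPKM on a log axis (vertical) of photoreceptor genes (chp, trp, inaC, ninaC and Arr2) and glial genes (Gs2, nrv2, alrm, repo and loco) in each of the 7 RNA libraries (horizontal). chp reached 98.3 and 186 RPKM in 60 h replicates 1 and 2 and 19.7 RPKM in replicate 3; Gs2 reached 220 and 825 RPKM in the 72 h libraries.

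In this step 2290 genes passed the threshold, 1150 higher and 1140 lower, and camera called 6 lists (0 with an estimated correlation). Without 60 h replicates 1 and 2, chosen after seeing the data, 1013 genes passed (554 higher and 459 lower), and without 72 h replicates 1 or 2 in turn the counts were 1559 and 1953. Of 88 named genes past the threshold 24 lost their call without 60 h replicates 1 and 2, among them bab2, dac, hth, VAChT, norpA, chp, crol, crq and CG14186. With 60 h replicates 1 and 2 left out, 32 oxidative phosphorylation, 4 vacuolar ATPase, 9 presynaptic and 3 glial genes rose, and 12 proteasome and 17 adhesion genes fell. Without 72 h replicate 2, 6 glial genes rose. Median, mean and camera direction differed in sign for dpr genes (0.16, -0.10 and down) and activity-regulated genes (0.02, -0.59 and down).

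**Figure D3:**
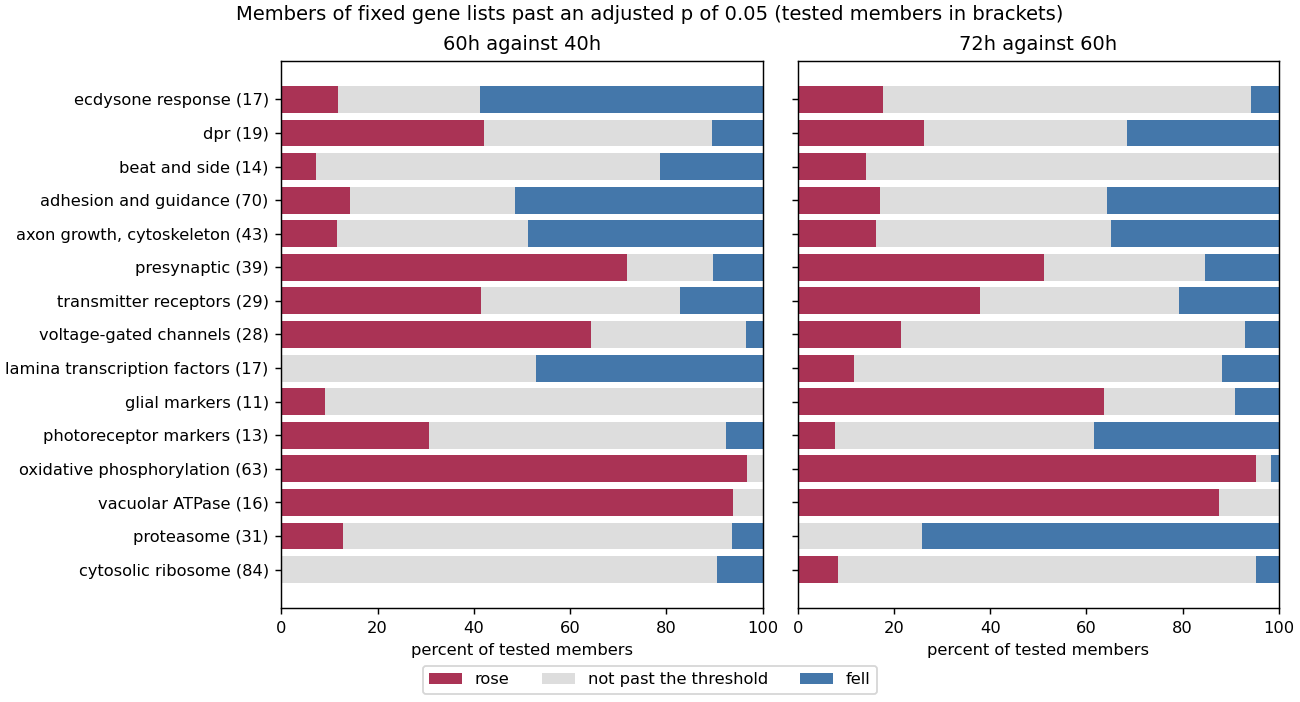
Percent of the tested members of 15 gene lists (horizontal axis) that rose, did not pass the threshold or fell (stacked bars) from 40 h to 60 h and from 60 h to 72 h. Of 63 oxidative phosphorylation genes 61 and 60 rose in the 2 steps, and of 31 proteasome genes 23 fell in the second, while under quantile normalization 28 oxidative phosphorylation genes rose in the second step and the proteasome median of the first step turned to -0.17.

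Across the whole span from 40 h to 72 h, the pyruvate kinase gene PyK rose from 7.13 ± 1.6 (SD, n = 2) to 1063 ± 150 RPKM (SD, n = 2), a log2 change of 7.04 ± 0.18 (SE, adjusted p = 1.2e-09), and ort rose by 7.03 ± 0.27. PVRAP (6.98 ± 0.33) and jdp (6.72 ± 0.28) were also among the 8 largest rises. sNPF, which encodes a neuropeptide precursor, fell from 1324 ± 24 to 12 ± 1.1 RPKM, Oatp26F from 1403 ± 96 to 6.72 ± 0.20 RPKM and the small heat shock gene Hsp67Bc from 3137 ± 80 to 18.9 ± 8.2 RPKM. nAChRalpha7 (-5.75 ± 0.31), Df31 (-5.54 ± 0.23) and mthl5 (67.1 to 0.493 RPKM) fell as well.

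Over this span the adhesion and guidance list had 12 rises and 39 falls among 70 genes (12 and 40 adjusted over the list alone; median -0.59, camera adjusted p = 2.9e-04; adjusted p = 0.14 with an estimated correlation). N-cadherin (CadN) fell from 110 to 8.14 RPKM, and rst, an adhesion protein of the immunoglobulin family, from 172 to 11.3 RPKM. Axon growth genes had 8 rises and 24 falls among 43 (median -0.68, camera adjusted p = 0.0015; adjusted p = 0.14 with an estimated correlation). Presynaptic genes had 28 rises and 6 falls among 39 (median 0.91, camera adjusted p = 8.9e-05), and channel genes 20 rises and 1 fall among 28 (median 1.16, camera adjusted p = 1.0e-04). Both calls had adjusted p = 0.49 with an estimated correlation. Every tested oxidative phosphorylation gene (63) and vacuolar ATPase gene (16) rose, with medians of 1.67 and 1.91 (camera adjusted p = 4.2e-23 and 2.5e-08; adjusted p = 0.39 with an estimated correlation for each). Of 31 proteasome genes 19 fell and 0 rose (median -0.36, camera adjusted p = 2.9e-04; adjusted p = 0.53 with an estimated correlation), and 30 fell under quantile normalization (median -0.73). Glial genes had 8 rises and 1 fall among 11 (median 2.22, camera adjusted p = 0.031; adjusted p = 0.49 with an estimated correlation), a list call lost without 40 h replicate 1 or 72 h replicate 2.

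Camera did not call the remaining lists over this span, but several were called in other settings: transmitter receptors without 40 h replicate 2 (camera adjusted p = 0.041), ribosome genes under quantile normalization (camera adjusted p = 1.4e-11), and 6 lists with fry (ecdysone response, dpr, transmitter receptor, lamina neuron transcription factor, other lamina neuron and activity-regulated genes). Ecdysone response genes had 2 rises and 9 falls among 17 (camera adjusted p = 0.105), with ftz-f1 at 5.25 ± 0.21 and Hr3 at -1.10 ± 0.35 (adjusted p = 0.020, lost without 40 h replicate 2 or 72 h replicate 1). Ribosome genes had 8 rises and 17 falls among 84 (6 and 13 adjusted over the list alone; camera adjusted p = 0.35), and 75 fell under quantile normalization, where RpL21 turned from 0.62 to -0.11. Over this span 4115 genes passed, 2097 higher and 2018 lower, and 3808 without 60 h replicates 1 and 2. Median, mean and camera direction differed in sign for beat and side (-0.12, 0.31 and up), photoreceptor (-0.04, 0.11 and up), heat shock (0.21, -0.55 and down) and activity-regulated genes (0.19, -0.56 and down).

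Chromatin at ftz-f1 opened between 40 h and 60 h more than at other peaks past the threshold. The peak at 3L 18783585 to 18784232, 17077 bp from the start of ftz-f1, went from 5.03 ± 0.15 to 170 ± 3.0 RPKM (SD, n = 2 each), by 4.82 ± 0.21 on the log2 scale (SE, adjusted p = 2.4e-06). A second ftz-f1 peak at 3L 18781300 to 18782299 opened by 4.52 ± 0.21 (5.76 to 154 RPKM). Peaks nearest to app (3L 12233099 to 12233942, 3.94 ± 0.21) and at the start of CG12769 (2R 8058412 to 8058906, 3.49 ± 0.20) opened next. The nearest genes given for the largest closings were noncoding RNA genes: lncRNA:CR46113 (3R 30270600 to 30271686, -4.88 ± 0.31), lncRNA:let7C, the host of let-7 (2L 18468253 to 18469065, -4.65 ± 0.25), lncRNA:CR43174 (3L 17931802 to 17932550, -4.50 ± 0.38) and lncRNA:CR45392 (3L 18079778 to 18080542, -4.34 ± 0.30). The CR43174 and CR45392 peaks lay on either side of a closing Eip75B peak (3L 17989259 to 17989693). Which gene a peak acts on was not tested.

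At the other ecdysone regulators the peak with the smallest p differed in direction. A peak at the start of Hr3 opened by 1.93 ± 0.20 (2R 10233506 to 10234980), and a peak of Eip93F by 1.93 ± 0.20 (3R 21992122 to 21992527). Another Hr3 peak (2R 10224470 to 10226477) was lower at 60 h (186 and 175 RPKM) than at 40 h (270 and 355 RPKM). Peaks of EcR (2R 6095440 to 6096733, -1.60 ± 0.20), Eip74EF (3L 17610973 to 17611346, -2.42 ± 0.23) and Eip75B (3L 17989259 to 17989693, -2.41 ± 0.22) closed. The Eip93F, EcR, Eip74EF and Eip75B peaks lay 43008, 35108, 7979 and 75003 bp from the start of their gene. In this step 6272 of 23508 peaks passed, 2518 higher and 3754 lower. Leaving out 60 h replicate 1 gave 10564 peaks, 58.3% of them higher against 40.1% with both 60 h libraries, and leaving out 40 h replicate 2 gave 3526.

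**Figure D4:**
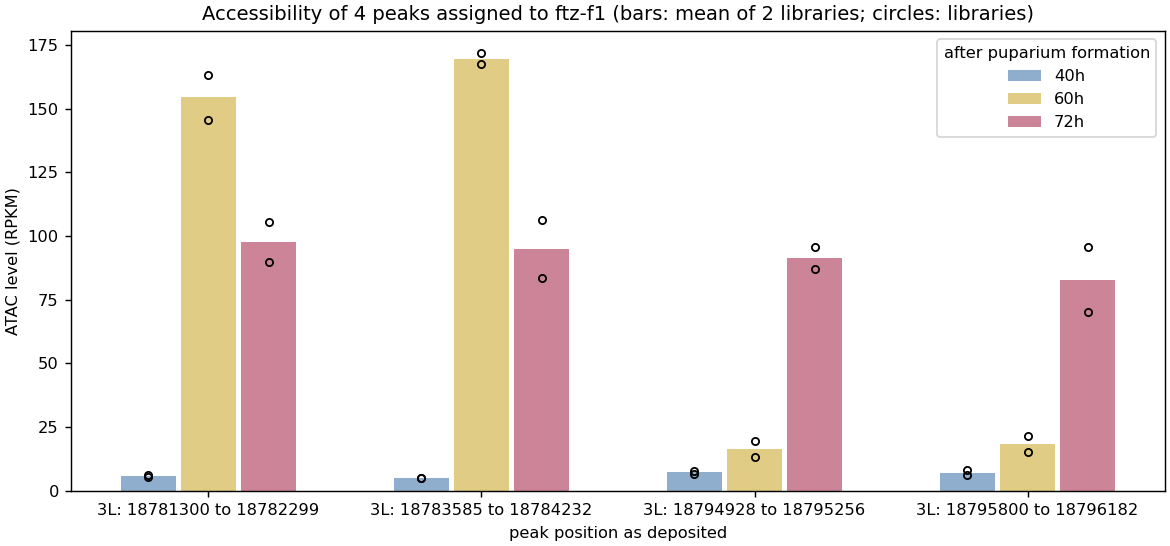
ATAC level in RPKM (vertical axis) of 4 peaks assigned to ftz-f1 at 40 h, 60 h and 72 h (horizontal axis); bars are means of 2 libraries and circles are libraries. The peak starting at 18783585 went from 5.03 to 170 RPKM by 60 h, and the peak starting at 18794928 from 16.4 to 91.3 RPKM between 60 h and 72 h.

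Between 60 h and 72 h a different pair of ftz-f1 peaks was among the 4 largest openings. They lay at 3L 18794928 to 18795256 (2.43 ± 0.31, adjusted p = 0.0063; 16.4 ± 4.6 to 91.3 ± 6.1 RPKM) and 3L 18795800 to 18796182 (2.12 ± 0.33; 18.3 to 82.8 RPKM). Peaks of CG43373 (3L 16522331 to 16522673, 2.95 ± 0.32) and dally, a heparan sulfate proteoglycan gene (3L 8823694 to 8824693, 2.08 ± 0.22), opened as well. The ftz-f1 pair that had opened by 60 h was lower at 72 h, with means of 170 and 154 RPKM at 60 h and 94.8 and 97.5 RPKM at 72 h. At the start of Shawl, whose RNA fell in this step, the peak at 2L 9414853 to 9415442 closed from 107 ± 8.1 to 22.9 ± 1.1 RPKM (-2.17 ± 0.20). A pair of peaks of the homeobox gene ct (X 7629322 to 7629844 and X 7629061 to 7629320) closed by -2.31 ± 0.26 and -2.26 ± 0.26, and a peak of tou (2R 11596463 to 11598193) by -2.24 ± 0.24. Among ecdysone regulators, peaks of EcR (2R 6121885 to 6122545, 1.13 ± 0.23), Eip74EF (3L 17584505 to 17584965, 1.70 ± 0.27) and Eip75B (3L 18027429 to 18027643, 1.41 ± 0.28) opened. Peaks of Hr3 (2R 10224470 to 10226477, -0.88 ± 0.19) and Eip93F (3R 21965553 to 21966134, -1.72 ± 0.20) closed. Each of these was a different peak from the smallest-p peak named at that gene for the first step. The EcR, Eip74EF and Eip75B peaks that had closed by 60 h stayed low. Their 72 h libraries had 67.0 and 68.0, 31.1 and 20.8, and 32.6 and 30.8 RPKM, against means of 252, 188 and 157 RPKM at 40 h.

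In this step 1201 peaks passed, 170 higher and 1031 lower, so that 14.2% were higher; under quantile normalization 1642 passed and 25.1% were higher. The count ranged from 218 without 72 h replicate 2 to 6199 without 60 h replicate 2 (3377 higher and 2822 lower). With only the 60 h and 72 h libraries in the limma fit 0 peaks passed, the 13 named ones included, where 5157 had unadjusted p under 0.05; voom on the 3 ages called 915. Without 72 h replicate 2, 6 of the 13 named peaks lost their call, among them both ftz-f1 peaks.

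From 40 h to 72 h 13016 peaks passed, 6108 higher and 6908 lower, a balance that differed for the 50% of peaks with the highest mean level (2193 and 5433) and without 40 h replicate 2 (2379 and 4455). The largest openings held 3 of the ftz-f1 peaks (3.98 ± 0.21, 3.86 ± 0.21 and 3.49 ± 0.31) and a peak near CG7560 (3L 11418437 to 11418652, 3.57 ± 0.44). Among the largest closings were the peaks of lncRNA:CR46113 (-4.97 ± 0.31) and lncRNA:CR45392 (-4.34 ± 0.30) and a peak of the growth factor gene Pvf3 (2L 7103928 to 7105497, -4.26 ± 0.29). The smallest-p Hr3 peak over this span (2R 10224470 to 10226477) closed too (-1.66 ± 0.19). Leaving out 40 h replicate 2 gave 6834 peaks and leaving out 72 h replicate 2 gave 8667.

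The median peak change was higher for genes whose RNA rose than for genes whose RNA fell, over 5149 genes with 14795 peaks. From 40 h to 60 h the median of the mean peak change was 0.11 for 1392 risers, -0.15 for 1162 fallers and -0.0002 for 2595 genes that did not pass. The difference of 0.26 had permutation p = 1e-05, the smallest that 100000 resamples can give, and 1e-05 after adjustment over the 3 comparisons. From 60 h to 72 h the medians were -0.07, -0.22 and -0.11 and the difference 0.15, and from 40 h to 72 h they were -0.01, -0.28 and -0.09 and the difference 0.27, each with the same permutation p. Under quantile normalization the risers' medians in the last pair of comparisons turned to 0.03 and 0.16, and with loess centring to 0.04 and 0.10. Without 60 h ATAC replicate 2, chosen after seeing the data, the medians of risers and fallers were 0.19 and -0.06 in the first step (difference 0.25) and -0.15 and -0.32 in the second (0.17). Pearson's r across genes was 0.39, 0.27 and 0.31 (Spearman's rho 0.29, 0.19 and 0.23); genes are not independent replicates.

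**Figure D5:**
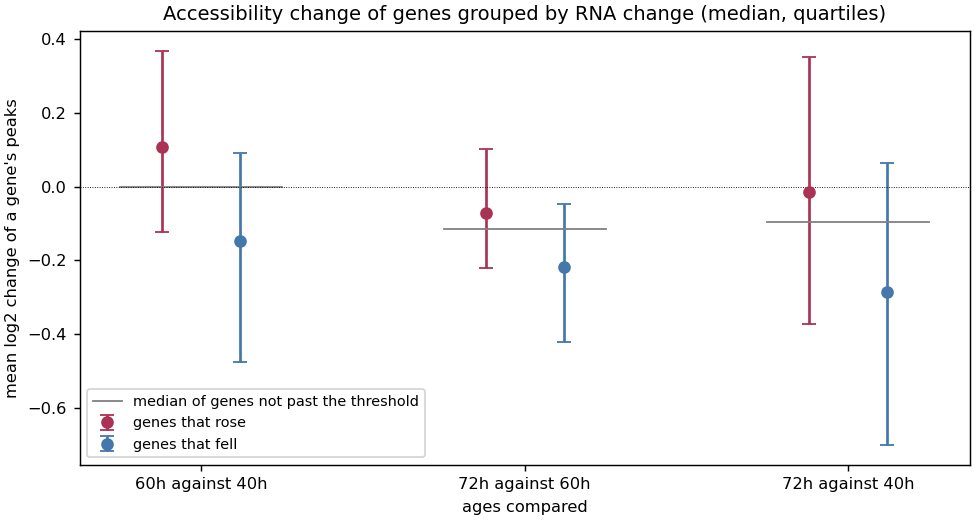
Median and quartiles of the mean log2 ATAC change of a gene's peaks (vertical axis) for genes whose RNA rose or fell, with a grey line for genes not past the threshold, in 3 comparisons (horizontal axis). The medians of risers and fallers were 0.11 and -0.15, -0.07 and -0.22, and -0.01 and -0.28; under quantile normalization the risers' medians of the last pair turned to 0.03 and 0.16.

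Of the genes tested, 1455 were called in both steps. There were 593 genes that rose and rose again, as Syngr, Vha13 and ort did, where independent lists would share 290, and 476 that fell and fell again (257), as Hsp23 did. wry, dpr5 and Con were among 237 that rose and then fell (287), and Hr4 and Hr39 among 149 that fell and then rose (259). In simulations of unchanged groups sharing the 60 h libraries the mean counts were 0, 0, 0.06 and 0.05. Unchanged groups give almost no calls at an adjusted p under 0.05, so these counts are no measure for the 1455. At an unadjusted limma p under 0.05 a mean of 57.7 simulated genes passed in both steps, 55.6 of them in opposite directions. Requiring a log2 change of at least 1 in both steps gave 108, 113, 85 and 75 genes in the data (independent lists 55.2, 43.1, 43.8 and 54.4). Without 60 h replicates 1 and 2, 579 genes were called in both steps (243, 170, 92 and 74 in the same order, where independent lists would share 93.7, 63.2, 77.7 and 76.2). For ATAC 682 peaks were called in both steps: 52 opened in both (independent lists 18.2), 459 closed in both (165), 139 opened and then closed (110) and 32 closed and then opened (27.1). Because the steps share the 60 h libraries, the comparison with independent lists is not a test.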

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

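Chosen only after the data were seen were the tests with voom, with loess centring, without chromosomes Y and 4, without 60 h RNA replicates 1 and 2, without 60 h ATAC replicate 2 in the join of peaks and RNA, and with a block of exchanged replicate numbers. The counts of RNA calls (3312, 2290 and 4115 for 60 h against 40 h, 72 h against 60 h and 72 h against 40 h) stayed within 1.5 times under both pseudocounts, both other filters, quantile and median-ratio scaling, the replicate block (3027, 2099 and 4061), voom and fits of only the ages compared. Requiring a log2 change of at least 1 gave 1591, 857 and 2495, as fewer genes can meet that limit. Without 60 h replicates 1 and 2 the 2 steps gave 2129 and 1013. Leave-one-out gave 2705 to 3363, 1559 to 2380 and 3544 to 4006; an age with 1 library left is assumed to vary like the others. Checks of named genes numbered 5412 over 322 results. Of these, 5159 kept their direction and side of the threshold, 230 kept direction and lost the call, 22 gained one, and 1 reversed: RpL21 from 40 h to 72 h, 0.62 as deposited and -0.11 ± 0.11 under quantile normalization (the cause was not tested). Of 273 named gene results past the threshold, 196 kept their call in every setting that tested the gene. Stricter filters left some genes untested.

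The ATAC counts (6272, 1201 and 13016) were less stable. The 50% of peaks with the highest mean level gave 3805 in the first step and 7626 over the span, with fewer peaks tested. A log2 change of at least 1 gave 4093, 720 and 7791. Loess centring gave 616 for 72 h against 60 h, quantile normalization 1642 (25.1% higher, against 14.2% as deposited) and the replicate block 6480, 1511 and 13332 (the cause was not tested). A block with the 40 h numbers exchanged, tried because within-age differences of 40 h and 60 h libraries ran opposite (r = -0.47 across peaks) and those of 60 h and 72 h alike (0.55), gave 9509 and 4723 in the steps. With only 60 h and 72 h libraries limma called 0 peaks, where 5157 had unadjusted p under 0.05 and voom on the 3 ages called 915; such limma fits of the other 2 comparisons called 5953 and 14844, and the cause was not tested. Leave-one-out gave 3526 to 10564, 218 to 6199 and 6834 to 14904. For 60 h against 40 h the counts beyond 1.5 times were 3526 without 40 h replicate 2 and 10564 without 60 h replicate 1. For 72 h against 60 h they were 369 without 40 h replicate 2, 525 without 60 h replicate 1, 6199 without 60 h replicate 2, 515 without 72 h replicate 1 and 218 without 72 h replicate 2. For 72 h against 40 h they were 6834 without 40 h replicate 2 and 8667 without 72 h replicate 2. Of 39 named peak results, 26 kept their call in every setting that tested the peak, and the 13 others were the named peaks of 72 h against 60 h.

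Camera called 8, 6 and 8 lists at its preset correlation and 0, 0 and 0 with an estimated correlation, where fry, which tests the members alone, called 10, 9 and 14. The estimated correlation of axon growth genes was -0.006, below the preset 0.01. Their camera adjusted p for 60 h against 40 h still went from 4.3e-04 to 0.099. Correlation between members therefore does not account for every call lost with the estimate. The replicate block gave 9, 8 and 8 lists and leave-one-out 8 to 10, 5 to 8 and 7 to 9. Quantile normalization gave 11, 7 and 9, adding the ribosome list in each comparison (medians -0.33, -0.36 and -0.68), the proteasome list (-0.17) and transmitter receptors (0.35) in the first and other lamina neurons (0.91) in the second, and ending the presynaptic call of 72 h against 60 h (median 0.17). The photoreceptor list gained calls with the replicate block (1.45 in the first step and -1.49 in the second), with the same medians as without 60 h replicate 3. The difference in peak change between genes that rose and fell stayed above 0 in every setting run (0.11 to 0.28). Genes called in both steps fell to 381 with a log2 change of at least 1 in both and to 579 without 60 h replicates 1 and 2, from 1455; peaks fell to 308 with that limit and 388 with loess centring, from 682. Neither the test of motif sites nor its 3 other settings were run without a genome sequence, and the count model named in advance for ATAC was not run because the deposited values are RPKM; voom on recovered reads gave 6180, 915 and 12828. Depth did not limit most genes or peaks, with medians of 1132 and 296 reads, whereas changes of 1.5-fold were recovered for at most 18 of 50 simulated RNA features and 9 of 50 ATAC features.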

Other observations

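The gene groups in the next paragraphs, and every test of an explanation below except that of a later age of the pupae, were chosen only after the values were seen, so no p is given for the groups. Of 11 glycolysis genes, 1 or more for each of the 10 enzymes from hexokinase to pyruvate kinase, 10 rose and 1 fell from 40 h to 60 h (median log2 change 1.97), where 25.1% of the 6928 other genes rose. From 60 h to 72 h 11 of 11 rose (median 1.68, against 16.4% of other genes), and 10 of 11 did so under quantile normalization. PyK, which catalyses the last step, went from 7.13 ± 1.6 RPKM (SD, n = 2) through 195 ± 33 (n = 3) to 1063 ± 150 (n = 2). Ald1 went from 20.7 through 202 to 479 RPKM and Gapdh2 from 350 through 1476 to 2168 RPKM. The hexokinase gene Hex-A fell by 1.19 ± 0.15 (SE) on the log2 scale and then rose by 1.94 ± 0.15. At 72 h 0 of the 11 genes were higher in replicate 2, the library with more glial transcripts, than in replicate 1 (median difference -0.31).

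Of 11 transcripts of the mitochondrial genome 2 rose from 40 h to 60 h, mt:CoI (0.71 ± 0.18) and mt:CoIII (0.58 ± 0.19), with a median of 0.50 over the 11. From 60 h to 72 h 10 of them rose (median 1.15). Under quantile normalization 5 rose, and 8 and 7 rose without 72 h replicate 1 and without 72 h replicate 2. At 72 h 8 of 11 were higher in replicate 2 than in replicate 1 (median difference 0.25). mt:CoI, a subunit of cytochrome c oxidase, went from 1012 ± 250 through 1644 ± 300 to 3193 ± 94 RPKM. The RNA was labelled polyA, and how transcripts of that genome enter such libraries was not measured.

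Photoreceptor genes in the 60 h RNA libraries did not follow the labelled age alone. The median range of 13 members over the 3 libraries was 2.06 on the log2 scale (99th percentile of 10000 level-matched random lists 0.613). If libraries of 1 label were alike in age, this argues against the age of L1 as the whole source. Unequal staging was not measured, and the random lists did not keep the members' correlation, estimated at 0.66. Across all genes tested, replicate 3 correlated with the 72 h libraries at 0.919 and 0.921, replicate 2 at 0.912 and 0.910 and replicate 1 at 0.898 and 0.897. A later stage of replicate 3 therefore stays open, although chp and trp were highest in replicate 2 and not in replicate 1. After quantile normalization replicates 1 and 2 still exceeded replicate 3 by 1.33, which argues against library scaling. Reads from photoreceptor cells carried through the FACS sort stay open: replicates 1 and 2 exceeded replicate 3 by a median of 1.40 (11 of 13 members), a grouping picked from these values, with the most abundant genes chp and trp at 186 and 124 RPKM in replicate 2. In 40 h replicate 2 and 72 h replicate 2, 13 of 13 members were above replicate 1 (median 1.01 and 1.39). Of the 13 genes 9 had at least 1 RPKM in every L1 library and 0 stood in another list. Reads carried over in every sort would give such levels too, so the count cannot tell them from expression by L1 itself, which stays open.

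Glial genes at 72 h differed between the 2 libraries. Of 11 members 8 were at least 2-fold apart (99th percentile of random lists 3). If both libraries were alike in age, this argues against the age of L1 as the whole source. Unequal staging was not measured, and the random lists did not keep the members' correlation, estimated at 0.27. However, 8 of 11 were higher in both 72 h libraries than in every 60 h library. A lower share of L1 among the cells at 72 h would raise other markers alike and stays open: lists of other lamina neurons and of GABAergic and monoaminergic neurons had medians of 0.98 and 0.87 from 60 h to 72 h, while the photoreceptor list had -0.86, but -0.41 with 1 of 13 members lower without 60 h replicates 1 and 2. The hemocyte list had a median of 0.12, with 1 of 4 tested members higher and 1 lower, and VGlut, the 1 glutamatergic marker, rose by 0.95. Reads from glia that passed the sort stay open too: replicate 2 exceeded replicate 1 by a median of 1.13 (10 of 11 members), which is the pattern itself, and Gs2 and nrv2 reached 825 and 335 RPKM. Of the 11 genes 6 had at least 1 RPKM in every library and 0 stood in another list, and of 1150 genes called higher at 72 h 78 were at least 2-fold higher and 7 at least 2-fold lower in replicate 2, 77 of the 78 being among 478 called higher by at least 2-fold (250 of all 6939 genes were at least 2-fold higher), so whether part of that list of rises has this source stays open.

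The ATAC libraries at 60 h differed along the axis of age. The difference of replicate 2 from replicate 1 correlated across peaks with the change from 40 h to 72 h (0.448), and still did within bins of 60 h level (0.457), which argues against a trend with level alone. A later age of the pupae behind replicate 2 could not be settled. With the 60 h level matched, 139 peaks that opened and then closed differed by -0.091 (99 of them lower). The 52 that opened in both steps differed by 0.059, and both values were short of the 0.1 set in advance. Outside that test, 459 that closed in both steps differed by -0.17 (384 lower). These classes came from calls whose spread includes the difference between these 2 libraries, so peaks with a large difference were less likely to enter. Lower contrast of peaks over background in replicate 2 cannot be told apart from age either, since the 10% of peaks with the highest level held 35.3% of its reads and 36.9% of those of replicate 1, between 38.4% and 41.1% at 40 h and 30.6% and 29.1% at 72 h.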
